A study of Mus musculus with 30 samples.

How the data were processed

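RNA was measured in CD11b-selected cells from the lumbar spinal cord of mice. Per the labels, mice were perfused with cold PBS, the tissue was dissociated by hand, and magnetic sorting (MACS) removed myelin before the CD11b selection. RNA was extracted with a micro-scale column kit, and libraries were made with Smart-Seq2, a full-length cDNA method, and the Nextera XT kit. The deposited table held 1 column per sample for 30 samples, and the authors gave its values as FPKM. The authors' processing notes name HISAT2 2.0.5.1, Cufflinks 2.2.1, featureCounts 1.4.6, DESeq2 with no version, and the genome build mm10. They do not say which tool made the FPKM values, which annotation was used or whether values were filtered. The column sums ran from 298889 to 491729, so the values were not on a common sum, and no further scaling was applied. Rat cultures named in the series description are not in this table. No gene positions are given, because the table holds symbols only.

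The table had 24888 rows. The 826 rows that shared 281 repeated symbols were left out, because they could not be told apart. Genes with an FPKM of at least 1 in at least 2 of the 30 libraries were kept, which left 11759. Values were taken as log2(FPKM + 1). Some genes with high values elsewhere are listed at exactly 0 in single libraries; a value of 0 in an FPKM table can be an estimate that failed as well as an absence of reads, so such values are given as listed at 0 and no fold is given against a group at 0, apart from 1 fitted difference of Clk2 that a rule set beforehand flagged.

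The files give no counts and no depth, so no counting interval or detection limit was computed. As a relative measure of depth, the nonzero FPKM of each library was multiplied by transcript length in kilobases (the longest transcript of each gene in the annotation) and the 5th percentile was taken as the floor. It compares libraries and gives no absolute depth. Correlation between libraries on the log2 scale was 0.789 to 0.988 within groups and 0.758 to 0.988 between groups. The highest value between groups was that of SNT_7dpi replicate 2 with CCI_2dpi replicate 1, at 0.988. The lowest within groups was that of SNT_7dpi replicate 1 with replicate 2, at 0.789. No pair of libraries shared more than 1 identical value, so no column was a copy of another. This does not exclude that the same RNA was sequenced more than once or that labels were exchanged. The first 2 principal components held 39.2% and 9.66% of the variance.

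Samples fell into 12 groups by their titles and treatment labels, and all 12 groups had their own mean wherever all 30 libraries entered a fit. Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend and two-sided moderated tests (F-tests for comparisons of more than 2 groups), and the Benjamini-Hochberg adjusted p had to be under 0.05. Each injury group was compared with all 9 controls, which share the title of control, in 1 fit of the 14 injury libraries and the controls. Each morphine group was compared with the saline group of its regimen in a fit of the 7 morphine and 7 saline libraries. The kinds of control, and the injury response against the morphine response, were tested in a fit of all 30 libraries. These comparisons, the filters, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

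Of 29 gene lists covering microglial states, cellular processes and markers of other cell types, those with at least 3 tested genes entered the tests. The list of mitochondrially encoded genes had 0 tested genes, T and NK cells 2, oligodendrocyte precursors 1 and red blood cells 1. Each list was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, and p-values were adjusted over the lists of a comparison. Members were also counted when adjusted over the list alone. The lists of other cell types include genes that microglia can express, so a shift in a list does not by itself count cells.

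Named genes were chosen by rule. Among called genes with a mean of at least 5 FPKM in either group and no overlap between the groups, the 10 largest differences in each direction were named. Where none passed, the 5 lowest p-values in each direction were available as not past the threshold, of which the text gives some, and for F-tests and differences of differences the 10 lowest p-values. Up to 4 members of each list were available in the same way. P2ry12, Tmem119, Cx3cr1, Apoe, Mki67, Il1b, Tnf, Tlr4 and Oprm1 were read in every comparison against controls. Of these 9, only Mki67 was called in any of them, under fixed morphine. Where a count of called genes was 5 or fewer its genes are named whether or not they met the rule.

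The procedure was tested on simulated data in which 200 of 11759 genes were changed. For fixed morphine against fixed saline it recovered 29.9% of changes of 1 log2 unit, 94.0% of changes of 2 and 95.5% of changes of 3, with 5 false calls. For SNT_7dpi against controls it recovered 2.99%, 65.7% and 98.5%, with 2 false calls. In this simulation a test with 2 libraries in the injured group had little power for changes of 1 log2 unit. The simulation drew each gene independently, while the first principal component of the real libraries held 39.2% of the variance. Its shares recovered and its false calls hold for independent genes and can differ in the real libraries.

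Sample numbers in the titles were checked for pairing. Deviations of injured and naive libraries with the same number correlated across genes at -0.332 to 0.0948, and those of fixed morphine and saline at -0.274 to -0.0493. None was clearly positive, as pairing would give, and samples were treated as unpaired. The check is weak, since both numbers of a group of 2 give the same value and pairs with different numbers were not compared. The replicate number as a block was run as an alternative. The other alternatives set beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, quantile, median-ratio and TPM scaling, array weights, an added minimum of 1 log2 unit, other control libraries, all 30 libraries in the fit, and leaving out each library in turn. Chosen after seeing the data were the naive libraries as the control for morphine, the removal of transcript length and GC content, and leaving out 3 libraries with under 9000 detected genes. Fits that divided libraries by their Cst3 level, and a fit that left out 2 fixed-morphine libraries with high cell cycle genes, were also run during exploration and are not reported, because the libraries had been chosen by measured values.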

Results

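Gene expression was measured in microglia, the resident macrophages of the central nervous system, from the caudal lumbar cord of C57BL/6J mice. The cells were isolated with antibodies to CD11b, a surface integrin that monocytes and neutrophils also carry. The table held FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 30 libraries in 12 groups. The controls comprised 2 naive, 4 fixed-regimen saline and 3 escalating-regimen saline libraries. Nerve-injured mice gave 14 libraries, 2 per group: sciatic nerve transection (SNT) at 1, 2, 4 and 7 days post injury (dpi), chronic constriction injury (CCI) at 2 and 7 dpi, and spared nerve injury (SNI) at 7 dpi. Morphine was given on a fixed regimen (4 libraries) or an escalating regimen (3 libraries). The labels give no doses. They do not state that each library came from its own animal, so every p-value measures the spread between these libraries.

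The files give no read counts, so the depth is unknown. Between 8005 and 10427 genes per library had an FPKM of at least 1. SNT_1dpi replicate 1 had the fewest genes, followed by SNT_7dpi replicate 1 with 8466 and SNT_2dpi replicate 2 with 8763. A relative floor, the 5th percentile of the nonzero values multiplied by transcript length, falls as depth rises. It spanned 0.119 to 0.135 in fixed morphine and 0.350 to 0.539 in fixed saline, which do not overlap. It was 0.0977 to 0.269 in naive, 0.256 to 0.618 in escalating saline, 0.146 to 0.450 in escalating morphine and 0.0933 to 0.215 over the CCI and SNI libraries. Over the SNT libraries it was 0.149 to 0.599.

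The question asked of the controls was whether naive and saline-treated mice differed. Cst3, which encodes the abundant microglial protease inhibitor cystatin C, stood at 16975 and 17341 FPKM in the naive libraries and at 40841 to 65263 FPKM in the 7 saline libraries. Lars2, a mitochondrial leucyl-tRNA synthetase gene, had 3202 and 2163 FPKM in naive, 61.7 to 278 FPKM in fixed saline and 26.1 to 34.4 FPKM in escalating saline. Clk2, a kinase that acts on splicing factors, had 6.84 and 16.6 FPKM in naive and 3.81 to 4.81 FPKM in escalating saline, and was listed at 0 in all 4 fixed-saline libraries. The 3 kinds of control differed in 12 of 11759 genes (limma moderated F-test, adjusted p under 0.05). Among them, each at a mean of at least 5 FPKM, were Sun2, Lars2, Clk2, Rhoq, Smad4, Lrrc25, Carm1, Cenpb and Yipf2, with adjusted p from 0.0132 for Sun2 to 0.0357 for Yipf2. At an unadjusted p under 0.05 there were 1591 genes, against 588 expected by chance. Leaving out naive replicate 1 or naive replicate 2 gave 0 calls, leaving out saline_escalating replicate 8 or saline_fixed replicate 4 gave 51 and 33, and leaving out saline_fixed replicate 3, 5 or 6 gave 6, 7 and 7. Quantile normalization gave 78 calls, array weights 1033, and leaving out the 3 libraries with few detected genes 689.

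**Figure D1:**
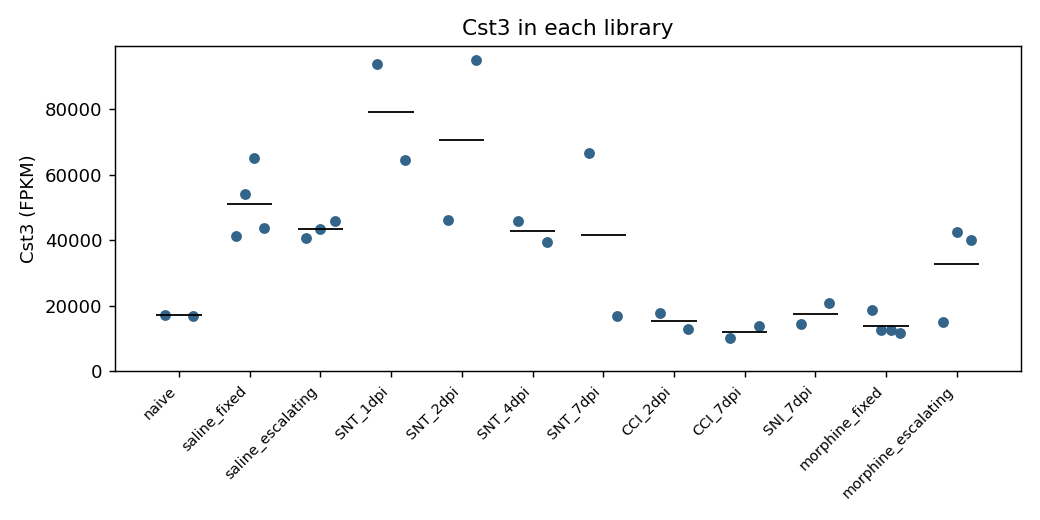
Cst3 in FPKM (vertical axis) for each of the 30 libraries by group (horizontal axis), with 1 point per library and a horizontal line at each group mean. The 4 fixed-morphine libraries lie between 11846 and 18574 FPKM, next to the naive libraries at 16975 and 17341 FPKM and below the fixed-saline libraries at 41317 to 65263 FPKM.

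After sciatic nerve transection the question was how the microglial transcriptome differed from the 9 controls on each day. At 1 dpi Xcl1, which encodes the chemokine lymphotactin, had 8.16 and 1.37 FPKM and was listed at 0 in all 9 controls (adjusted p = 0.00133, limma), and 1700084E18Rik had 5.97 and 2.26 FPKM against at most 1.17 FPKM in the controls (log2 fold change 1.99 ± 0.32, SE; adjusted p = 0.0185). These 2 genes were the only calls and are named because the count is small; both averaged under 5 FPKM, outside the rule for named genes. All 40 ribosomal protein genes had positive differences at 1 dpi, with a median of 1.05. Rps29 averaged 3347 ± 982 FPKM (SD, n = 2) against 928 ± 578 FPKM (n = 9), and Rpl38 averaged 427 ± 52.7 FPKM against 118 ± 79.4 FPKM. In a competitive set test against other genes (camera) the ribosomal list had an adjusted p of 2.6e-24 with a preset correlation, and adjusted p = 0.838 with an estimated correlation. None of its genes was called over all genes, and 16 were higher when adjusted over the list alone. The 3 libraries with the fewest detected genes had the 3 highest means of log2(FPKM + 1) over the ribosomal list of all 30 libraries (9.70 in SNT_1dpi replicate 1, 9.59 in SNT_2dpi replicate 2 and 9.58 in SNT_7dpi replicate 1) and the 3 highest Cst3 values. Without SNT_1dpi replicate 1 the ribosomal median at 1 dpi was 0.75. The neutrophil list had a median of -1.99 at 1 dpi with 13 of 13 members negative. Its most shifted members were Ngp (386 ± 504 against 1912 ± 1300 FPKM) and Elane (16.0 ± 22.7 against 105 ± 157 FPKM), both granule protein genes. It had an adjusted p of 1.2e-05, and adjusted p = 0.838 with an estimated correlation. None of its genes was called, and 8 were lower when adjusted over the list alone. The monocyte list had a median of -1.07 with 12 of 13 members negative, an adjusted p of 0.000102, and adjusted p = 0.838 with an estimated correlation. Both shifts rest largely on SNT_1dpi replicate 1, whose list means were 4.75 for neutrophils and 1.04 for monocytes, while replicate 2 had 7.55 and 2.93, within the ranges of the controls (7.13 to 9.59 and 2.49 to 4.79). Without replicate 1 the medians were -0.72 and -0.57. The oligodendrocyte list had a median of 0.03 and a mean of 0.40 (adjusted p = 0.0291, and adjusted p = 0.901 with an estimated correlation).

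At 2 dpi after transection no gene passed (limma, 0 calls, 862 genes at an unadjusted p under 0.05). The ribosomal list again had 40 of 40 positive members, with a median of 0.74 (adjusted p = 1.4e-26, and adjusted p = 0.701 with an estimated correlation), and 0.33 without SNT_2dpi replicate 2. Genes of glycolysis and hypoxia were negative in 21 of 22 cases, with a median of -0.60 (adjusted p = 0.00153, and adjusted p = 0.701 with an estimated correlation). Pkm, the pyruvate kinase gene, averaged 101 ± 95.6 FPKM against 187 ± 51.1 FPKM. The circadian clock list had a median of 0.10 (adjusted p = 0.0364, and adjusted p = 0.701 with an estimated correlation). The list of spinal microglia genes linked to neuropathic pain had a median of -0.61 with 21 of 26 members negative (adjusted p = 0.0386, and adjusted p = 0.701 with an estimated correlation). The glycolysis and neuropathic pain shifts rest on SNT_2dpi replicate 2, one of the libraries with few genes, whose list means were 3.38 and 5.82. Replicate 1 had 4.56 and 6.93, within the ranges of the controls (4.11 to 4.88 and 6.72 to 7.07). At 4 dpi no gene passed either (limma, 0 calls, 275 genes at an unadjusted p under 0.05). Immediate early genes had 19 of 22 negative members and a median of -0.36 (adjusted p = 7.9e-05, and adjusted p = 0.828 with an estimated correlation). The cell cycle list had medians of -0.91, -0.82 and -0.52 at 1, 2 and 4 dpi, with adjusted p of 0.00462, 3.9e-05 and 5.2e-08. With an estimated correlation these were adjusted p = 0.901, 0.701 and 0.928. The lowest cell cycle list means, 1.071 in SNT_1dpi replicate 1 and 1.169 in SNT_2dpi replicate 2, were in libraries with few genes. The other replicates of these groups had 1.565 and 1.418. SNT_4dpi had 1.701 and 1.486, where the controls had 1.614 to 3.072.

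At 7 dpi after transection 24 genes were called and all 24 were higher than in the controls (limma, adjusted p under 0.05). None was called with a pseudocount of 0.1, a filter of 5 FPKM, array weights or the replicate block, and more were called with no filter. Ckmt1, the mitochondrial creatine kinase gene, averaged 7.08 ± 4.59 FPKM (SD, n = 2) against 0.339 ± 0.462 FPKM (n = 9), a log2 difference of 2.53 ± 0.39 (SE; adjusted p = 0.00780). Penk, the precursor of enkephalin opioid peptides, averaged 6.11 ± 3.79 FPKM against 0.580 ± 0.62 FPKM, a difference of 2.15 ± 0.45 (adjusted p = 0.0453). Zcchc18, Tmem59l and Car11 differed by 2.41 ± 0.46, 2.40 ± 0.49 and 2.02 ± 0.33. All 24 genes were higher in 2 of 2 libraries than in all 9 controls, and these 5 were the only ones with a mean of at least 5 FPKM, as the rule for named genes asks. The neuron list, which holds none of the 5, had 9 of 10 positive members and a median of 0.52, with list means of 1.25 and 1.84, although saline_escalating replicate 9 had 2.43. Nefm, a neurofilament gene, averaged 6.56 ± 1.60 FPKM against 1.48 ± 1.94 FPKM. The list had an adjusted p of 0.0192, and adjusted p = 0.991 with an estimated correlation, and 1 gene was higher when adjusted over the list alone. The astrocyte list had a median of 0.61 (adjusted p = 0.165). The neutrophil list had a median of -0.74 (adjusted p = 0.0192, and adjusted p = 0.991 with an estimated correlation), which was 0.18 against naive controls alone and -0.05 without SNT_7dpi replicate 2. The count of SNT_7dpi against controls was 0 with naive controls alone, 6 with median-ratio scaling, 0 with TPM rescaling, 1006 without SNT_7dpi replicate 2, 42 without SNT_7dpi replicate 1, 8 without saline_fixed replicate 6, 11 without naive replicate 2, 15 without saline_escalating replicate 7, and 13 without naive replicate 1, saline_fixed replicate 3 or saline_fixed replicate 5.

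A test among the 4 SNT days, with no control in the contrast, called only Xcl1 (limma moderated F-test, adjusted p = 0.0459). At an unadjusted p under 0.05 there were 1350 genes. The spread in this test came from all 23 libraries of the injury fit, among them the controls, where Xcl1 was listed at 0. Leaving out SNT_2dpi replicate 1, SNT_1dpi replicate 2 or SNT_7dpi replicate 2 gave 546, 512 and 172 calls. Leaving out SNT_1dpi replicate 1 gave 2, and leaving out SNT_4dpi replicate 1 or SNT_7dpi replicate 1 gave 0. For the single days, leaving out SNT_1dpi replicate 2 gave 1221 calls for SNT_1dpi against controls, leaving out saline_fixed replicate 5 or saline_fixed replicate 6 gave 6 and 4 at 1 dpi, and leaving out SNT_2dpi replicate 1 gave 1143 at 2 dpi. Leaving out SNT_2dpi replicate 2 or saline_fixed replicate 5 gave 1 at 2 dpi, and leaving out SNT_4dpi replicate 2 gave 1 at 4 dpi.

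After chronic constriction injury 42 of 44 cell cycle genes had positive differences at 2 dpi and 42 of 44 at 7 dpi, with medians of 1.31 and 1.81. At 2 dpi Mcm6, a subunit of the replicative helicase, averaged 44.3 ± 3.96 FPKM (SD, n = 2) against 7.85 ± 3.70 FPKM in the 9 controls. At 7 dpi Mki67, the gene of the proliferation marker Ki-67, averaged 27.0 ± 29.6 FPKM against 2.09 ± 2.33 FPKM, and Foxm1, a mitotic transcription factor gene, averaged 14.2 ± 13.6 FPKM against 0.802 ± 1.37 FPKM. The replicates lay far apart, since Mki67 was 2.29 and 23.1 FPKM at 2 dpi and 47.9 and 6.06 FPKM at 7 dpi. Naive replicate 2 had 8.24 FPKM. The list had an adjusted p of 2.3e-13 at 2 dpi and 7.0e-23 at 7 dpi, and adjusted p = 0.332 and 0.272 with an estimated correlation. None of its genes was called over all genes. When adjusted over the list alone, 12 were higher at 2 dpi, and 35 were higher and 1 was lower at 7 dpi. Without CCI_2dpi replicate 2 the median at 2 dpi was -0.08, and without CCI_7dpi replicate 1 the median at 7 dpi was 0.71. The list mean of CCI_7dpi replicate 2 was 2.75, within the range of the controls.

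**Figure D2:**
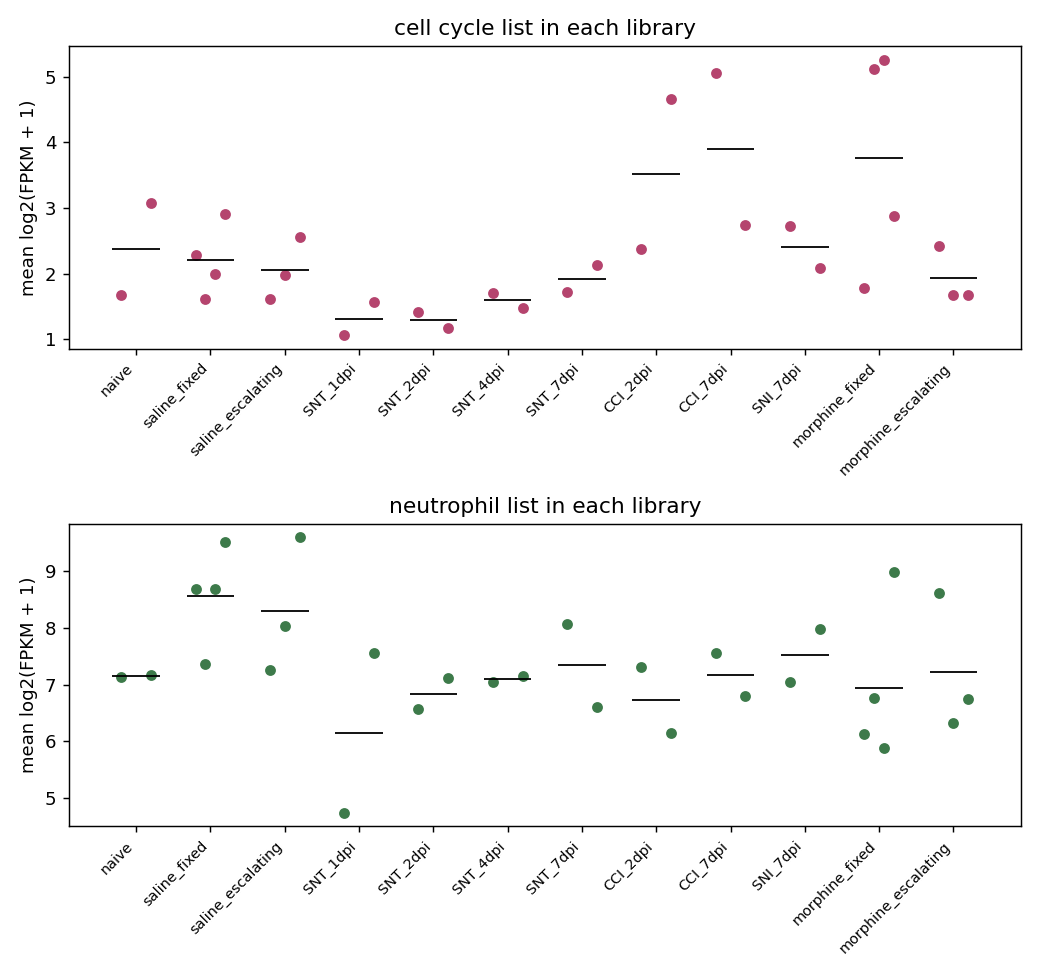
Mean log2(FPKM + 1) (vertical axes) of the cell cycle list (44 genes, upper panel) and of the neutrophil list (13 genes, lower panel) in each library by group, with 1 point per library and a horizontal line at each group mean. For the cell cycle, 1 CCI_2dpi, 1 CCI_7dpi and 2 fixed-morphine libraries lie at 4.67 to 5.26, while the 9 controls lie at 1.61 to 3.07.

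All 19 measured cholesterol synthesis genes had positive differences at 2 and at 7 dpi after constriction, with medians of 0.71 and 0.54. Sqle, a rate-limiting enzyme of the pathway, averaged 8.73 ± 0.758 FPKM at 2 dpi against 2.34 ± 1.39 FPKM. The adjusted p of the list was 0.000717 at 2 dpi and 0.0305 at 7 dpi, and adjusted p = 0.395 and 0.524 with an estimated correlation. The 7 dpi value rests on CCI_7dpi replicate 1, without which the median was 0.05; the list means of the replicates were 3.32 and 2.27, where the controls had 1.79 to 2.39. Glucocorticoid-induced genes had 18 of 21 negative members at 7 dpi and a median of -0.47 (adjusted p = 4.5e-05, and adjusted p = 0.266 with an estimated correlation). Among them Sult1a1, a sulfotransferase gene, averaged 18.5 ± 3.89 FPKM against 71.6 ± 24.2 FPKM, a difference of -1.85 ± 0.40. The heat shock list had 13 of 15 positive members at 2 dpi and a median of 0.58 (adjusted p = 0.0204, and adjusted p = 0.599 with an estimated correlation), and 0.17 without CCI_2dpi replicate 1. The ribosomal list had medians of -0.41 and -0.40, with adjusted p of 6.5e-06 and 7.7e-07, and adjusted p = 0.624 and 0.524 with an estimated correlation. The neutrophil list had medians of -1.49 and -1.08, with adjusted p of 1.4e-08 and 2.6e-05, and adjusted p = 0.280 and 0.416 with an estimated correlation. CCI_2dpi replicate 1 and CCI_7dpi replicate 1 had neutrophil list means of 7.31 and 7.55, within the range of the controls, and without replicate 2 of each group the medians were -0.81 and -0.69. At 7 dpi the astrocyte list had a median of -0.50 (adjusted p = 0.00833) and the endothelial and mural list a median of -0.75 (adjusted p = 0.0107), with adjusted p = 0.524 and 0.272 with an estimated correlation. The astrocyte list means were 2.21 and 1.33, both within the range of the controls (1.01 to 4.02). Against naive controls alone the neutrophil medians were -0.33 and 0.08 and the ribosomal medians 0.05 and 0.02. The endothelial and mural list means were 1.06 in both CCI_7dpi libraries and 0.99 and 1.04 in the naive ones.

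The only gene called after constriction was Pigb, a gene of GPI anchor synthesis, at 2 dpi (8.73 and 5.61 FPKM; adjusted p = 0.0118, limma). It was listed at 0 in all 9 controls and in most other libraries. At 7 dpi no gene passed (limma, 0 calls, 1146 genes at an unadjusted p under 0.05). The lowest p there, with an adjusted p of 0.269, included Htra3, a secreted serine protease gene (39.1 ± 0.943 against 6.74 ± 4.11 FPKM), Rspo1 (7.27 ± 0.548 against 1.58 ± 1.21 FPKM) and the Fc receptor gene Fcgr3 (324 ± 62.6 against 747 ± 168 FPKM). Without CCI_7dpi replicate 2, 100 genes were called at 7 dpi. Without naive replicate 2 there were 2 and without CCI_7dpi replicate 1 there was 1. At 2 dpi there were 0 calls without CCI_2dpi replicate 2, with a pseudocount of 0.1, with a filter of 5 FPKM, with quantile or median-ratio scaling, with naive controls alone and with the replicate block. There were 262 with array weights.

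After spared nerve injury 27 of 31 type I interferon genes had positive differences at 7 dpi, with a median of 0.62. CCI_7dpi had 24 of 31 and a median of 0.39 (adjusted p = 0.162). Ifit1 averaged 4.23 ± 2.06 FPKM (SD, n = 2) against 1.19 ± 0.638 FPKM (n = 9), Usp18 9.37 ± 1.48 against 3.90 ± 2.03 FPKM, and Parp14 8.33 ± 0.540 against 3.67 ± 1.64 FPKM. All 3 are interferon-stimulated genes. The list had an adjusted p of 3.2e-07, and adjusted p = 0.202 with an estimated correlation, the lowest such value of any list and comparison. No member was called over all genes or adjusted over the list alone. The median was 0.60 against naive controls alone, and 0.58, 0.65 and 0.85 with quantile, median-ratio and TPM scaling. The glucocorticoid list had a median of -0.34 (adjusted p = 0.0339, and adjusted p = 0.983 with an estimated correlation), with Sult1a1 at 21.6 ± 1.03 FPKM against 71.6 ± 24.2 FPKM. Npnt, an integrin ligand gene, averaged 29.8 ± 4.00 FPKM against 9.11 ± 2.92 FPKM (adjusted p = 0.999). No gene passed (limma, 0 calls, 478 genes at an unadjusted p under 0.05). Without SNI_7dpi replicate 1 there were 2.

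At 7 dpi the 3 injury models together (6 libraries) were set against the 9 controls. Htra3 averaged 24.8 ± 14.4 FPKM (SD) against 6.74 ± 4.11 FPKM, Rspo1 5.80 ± 2.19 against 1.58 ± 1.21 FPKM, and Sult1a1 42.6 ± 48.6 against 71.6 ± 24.2 FPKM, each with an adjusted p of 0.173. Sult1a1 was 34.1 and 141 FPKM in the SNT_7dpi libraries, so its lower mean rests on CCI and SNI. The homeostatic gene P2ry12, a purinergic receptor of resting microglia, averaged 1052 ± 323 FPKM against 1050 ± 193 FPKM, a difference of -0.03 ± 0.22 (adjusted p = 0.969). Tmem119 differed by 0.03 ± 0.29, Cx3cr1 by -0.38 ± 0.28, Apoe by 0.31 ± 0.31, Il1b by -1.25 ± 0.57, Tnf by -0.33 ± 0.29 and Tlr4 by 0.02 ± 0.51, and none of them passed. Oprm1, the mu opioid receptor gene, was listed at 0 in all 6 libraries and averaged 0.506 ± 0.769 FPKM in the controls. The cell cycle list had 41 of 44 positive members and a median of 0.58 (adjusted p = 4.6e-05, and adjusted p = 0.953 with an estimated correlation), and 0.22 without CCI_7dpi replicate 1. The monocyte list had a median of -0.83 with 13 of 13 members negative (adjusted p = 7.7e-06, and adjusted p = 0.627 with an estimated correlation), and 0.15 against naive controls alone. The neutrophil list had a median of -0.87 (adjusted p = 4.6e-05, and adjusted p = 0.757 with an estimated correlation), and 0.28 against naive controls alone.

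No gene passed for injury at 7 dpi against controls (limma, 0 calls, 1396 genes at an unadjusted p under 0.05). Against the 7 saline controls alone there were 563 calls, and against the 2 naive controls alone 0, with 27 genes at an unadjusted p under 0.05. Without SNT_7dpi replicate 1 there were 437, without naive replicate 2 there were 140, without naive replicate 1 there were 64, without SNT_7dpi replicate 2 there were 12, and without saline_escalating replicate 9 or CCI_7dpi replicate 2 there was 1. A test among the 3 models at 7 dpi called 0 genes (limma moderated F-test, 456 at an unadjusted p under 0.05). The lowest adjusted p was 0.0945. Among genes that met the rule of at least 5 FPKM the lowest p were for Nop58 and Tcea2, with adjusted p of 0.480 and 0.492. Without SNT_7dpi replicate 2 there were 792, without CCI_7dpi replicate 2 there were 2, and without CCI_7dpi replicate 1 there was 1.

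**Figure D3:**
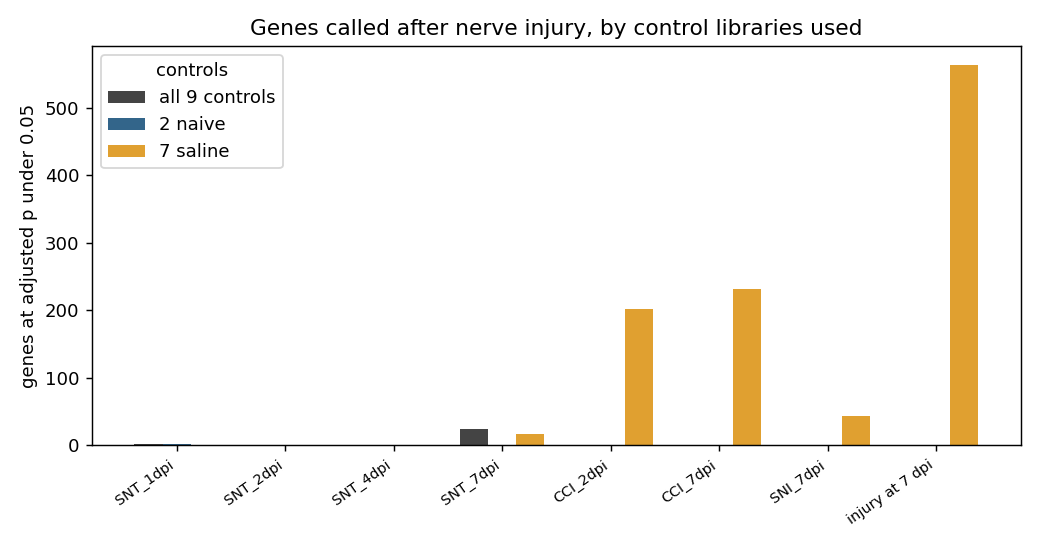
Number of genes called at an adjusted p under 0.05 (vertical axis) in each comparison of nerve injury with controls (horizontal axis), with bars for all 9 controls, the 2 naive libraries alone and the 7 saline libraries alone. CCI_2dpi gave 202 calls and CCI_7dpi 231 against saline alone, and both gave 0 against naive alone.

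At 2 dpi, transection and constriction were compared with each other. Cell cycle genes were lower after transection in 43 of 44 cases, with a median of -2.46, and ribosomal genes were higher in 38 of 40, with a median of 1.23. Mcm6 averaged 3.64 ± 3.53 FPKM after transection and 44.3 ± 3.96 FPKM after constriction, and Uhrf1 averaged 0.416 ± 0.128 and 13.9 ± 9.58 FPKM (SD, 2 libraries each). The adjusted p was 4.4e-15 for the cell cycle list and 6.3e-24 for the ribosomal list, and adjusted p = 0.328 and 0.289 with an estimated correlation. Adjusted over the list alone, 30 cell cycle genes were lower. The cell cycle median was -1.14 without CCI_2dpi replicate 2, and the ribosomal median was 0.72 without SNT_2dpi replicate 2. No gene passed over all genes (limma, 0 calls, 2107 at an unadjusted p under 0.05). For SNT against CCI at 2 dpi without SNT_2dpi replicate 1 there were 1779, and without SNT_2dpi replicate 2 or CCI_2dpi replicate 1 there was 1.

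Whether injuries resembled each other was asked by correlating their log2 differences across 11759 genes, which are not independent replicates. Groups that share controls correlate without any effect, and simulated unchanged groups gave a mean r of 0.182. The simulation drew each gene independently, while the first principal component of the real libraries held 39.2% of the variance. Libraries with such a shared structure can correlate more without any effect, so 0.182 accounts for the shared controls alone. CCI_2dpi with CCI_7dpi gave r = 0.872 (Spearman rho 0.861), CCI_7dpi with SNI_7dpi 0.807 (rho 0.800) and CCI_2dpi with SNI_7dpi 0.777 (rho 0.752). With the controls split between the groups these were 0.777, 0.687 and 0.663. SNT_1dpi with SNT_2dpi gave r = 0.486 (rho 0.430), and SNT_7dpi with CCI_2dpi 0.340 (rho 0.301). SNT at 1, 2 and 4 dpi correlated negatively with CCI and SNI, from r = -0.224 for SNT_1dpi with CCI_7dpi to -0.107 for SNT_2dpi with CCI_2dpi. The median r over all 21 pairs of groups was 0.131. Without SNT_7dpi replicate 1 it was -0.107, and without SNT_7dpi replicate 2 it was -0.138. Cst3 and the relative floor moved with the same groups, since both CCI groups and SNI had Cst3 at 10120 to 20827 FPKM and SNT at 1, 2 and 4 dpi had 39503 to 95123 FPKM.

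Fixed-regimen morphine was compared with fixed-regimen saline to ask how chronic morphine changed the microglial transcriptome. C4b, a complement component gene, rose from 0.816 ± 0.855 to 38.2 ± 33.0 FPKM (SD, n = 4 each), a log2 difference of 4.13 ± 0.73 (SE; adjusted p = 0.00606, limma). Slc39a14, a zinc and iron transporter gene, rose by 3.83 ± 0.59, Jdp2, an AP-1 repressor gene, by 3.35 ± 0.66, and Hspa1b, an inducible heat shock protein, by 3.18 ± 0.40. Ppp6r1 (3.95 ± 0.62), Snhg11 (3.57 ± 0.98), Cenpb (3.34 ± 0.52), Larp1 (3.22 ± 0.49) and the mRNA export gene Alyref (3.17 ± 0.49) rose as well. Clk2 averaged 13.9 ± 1.95 FPKM in morphine and was listed at 0 in all 4 saline libraries. S100a4, a calcium-binding protein gene, changed by -3.13 ± 0.52, Lag3, an immune checkpoint receptor gene, by -3.16 ± 0.53, the C-type lectin receptor gene Clec4d by -3.29 ± 0.69, Bri3 by -3.25 ± 0.65, the stress-induced factor Ddit3 by -3.89 ± 0.90 and Pigp by -3.22 ± 0.95. Gngt2, Slirp, Yipf2 and Polg2 were listed at 0 in all 4 morphine libraries and averaged 112 ± 48.6, 41.1 ± 17.6, 14.03 ± 3.16 and 10.7 ± 6.52 FPKM in saline. Ddit3 and Pigp averaged 2.73 ± 5.45 and 3.25 ± 6.50 FPKM in morphine, and Jdp2 averaged 0.200 ± 0.400 FPKM in saline. Most libraries of those groups were listed at 0 for these genes, so the sizes of their differences rest largely on such values. In the 2 naive libraries C4b had 19.1 and 13.5 FPKM, and Slc39a14 had 6.73 and 11.2 FPKM. Clk2 had 6.84 and 16.6 FPKM there. With the naive libraries as the control the differences of Jdp2 (-0.36), Hspa1b (-0.67), Ddit3 (0.89) and Lag3 (0.24) had the opposite sign.

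In total 2119 genes were called, of which 1595 were higher and 524 lower in fixed morphine. The libraries of the 2 groups did not overlap for 1957 of these genes and for 29.6% of all genes, where chance gives 2.86%. The median difference of all genes was 0.22, and -0.02, 0.11 and 0.53 with quantile, median-ratio and TPM scaling, which called 986 higher and 826 lower, 1300 and 675, and 3056 and 293. For morphine_fixed against saline_fixed 0 genes were called with the naive libraries as the control (limma, 615 at an unadjusted p under 0.05). None was called with the replicate block, where few libraries share a number. Fewer were called with all 30 libraries in the fit, and more with array weights. Without morphine_fixed replicate 2 or 3 the count was 757 and 831, and without saline_fixed replicate 5 or 6 it was 930 and 969.

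Among the fixed lists, 8 of 44 cell cycle genes rose under fixed morphine, 26 were higher and 1 lower when adjusted over the list alone, and the median was 1.67. Mki67 rose from 1.32 ± 0.474 to 26.7 ± 24.6 FPKM (difference 2.88 ± 0.71, adjusted p = 0.0171) and Foxm1 from 0.406 ± 0.170 to 15.4 ± 15.3 FPKM. The morphine replicates had 2.43, 51.9, 43.5 and 8.86 FPKM of Mki67. The list had an adjusted p of 0.000135, and adjusted p = 0.764 with an estimated correlation. Of 15 heat shock genes 5 rose, among them Hspa1a (1.12 ± 0.518 to 9.92 ± 4.64 FPKM), Hspa5 and Hspd1, and 10 were not called (median 0.47, adjusted p = 0.106). Hspa1a was 10.05 and 18.11 FPKM in the naive libraries. Of 17 cytokine and chemokine genes 5 rose and 2 fell. Ccl12, a monocyte chemoattractant, rose from 30.5 ± 11.9 to 244 ± 123 FPKM, Ccl2 from 3.01 ± 4.28 to 21.8 ± 18.0 FPKM and Tgfb1 from 14.4 ± 2.31 to 95.5 ± 9.04 FPKM, while Il6 fell from 5.03 ± 1.56 to 0.900 ± 0.501 FPKM (median of the list 0.12, adjusted p = 0.681). With the naive libraries as the control, the Tgfb1 difference averaged over both morphine regimens had the opposite sign. Of 31 interferon genes 5 rose, with Ifit2 up from 1.80 ± 1.00 to 7.60 ± 2.64 FPKM and Stat2 from 5.65 ± 1.70 to 13.5 ± 2.35 FPKM (median 0.49, adjusted p = 0.214). No list was called with an estimated correlation in this or any other comparison, although 89 were called over all comparisons with the preset one. In a rotation test of whether a list's genes moved, on balance, one way (fry), the lowest adjusted p was 0.0689, for the heat shock list here.

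Microglial identity genes moved in different directions under fixed morphine. P2ry12 differed by 0.13 ± 0.22, Tmem119 by -0.36 ± 0.21 and Cx3cr1 by -0.55 ± 0.21, and none of them passed. Siglech fell from 608 ± 43.3 to 294 ± 36.5 FPKM, Cst3 fell from 51090 ± 10964 to 13942 ± 3113 FPKM and Sall1, a transcription factor gene of microglial identity, rose from 49.5 ± 6.86 to 84.5 ± 9.35 FPKM. In the naive libraries Cst3 was 17341 and 16975 FPKM, within the range of the fixed-morphine libraries. Siglech, Cst3 and Sall1 were the 3 of 25 homeostatic genes called. The list's median was -0.10 (adjusted p = 0.00962, and adjusted p = 0.651 with an estimated correlation), and 0.16 and 0.19 with quantile and TPM scaling. Of 27 disease-associated microglial genes 1 rose (Csf1, 1.63 ± 0.803 to 8.62 ± 2.18 FPKM) and 6 fell, including Tyrobp (2489 ± 826 to 868 ± 112 FPKM) and B2m (3446 ± 407 to 802 ± 113 FPKM). The median was -0.08 (adjusted p = 0.00629, and adjusted p = 0.636 with an estimated correlation), and 0.22 with TPM scaling and 0.07 without saline_fixed replicate 6. Of 19 antigen presentation genes 5 fell, including the MHC class II genes H2-Eb1 (28.8 ± 5.97 to 6.03 ± 2.24 FPKM) and H2-Ab1 (60.6 ± 13.4 to 22.0 ± 6.60 FPKM), and 1 rose. The median was -0.29 (adjusted p = 0.00629, and adjusted p = 0.636 with an estimated correlation), and 0.01 with TPM scaling and 0.20 with the naive libraries as the control. Of 23 complement and phagocytic receptor genes 4 rose and 4 fell, with C1qa down from 3958 ± 661 to 1370 ± 92.3 FPKM and Itgam, which encodes CD11b, up from 226 ± 131 to 435 ± 18.4 FPKM (median 0.09, adjusted p = 0.419). Of 21 opioid receptor and TLR4 signalling genes 1 rose, the kinase gene Irak1 (10.1 ± 2.64 to 28.9 ± 3.54 FPKM), and the median was 0.09 (adjusted p = 0.741). Tlr4 differed by 0.98 ± 0.38 (adjusted p = 0.0819), and Oprm1 was listed at 0 in all 4 morphine libraries and in 3 of 4 saline libraries. Of 26 genes linked to neuropathic pain 3 rose and 3 fell (median -0.03, adjusted p = 0.245).

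Metabolic lists showed few calls under fixed morphine. The cholesterol synthesis list had a median of 0.66 (adjusted p = 0.0739). Of 15 lipid handling genes 1 was called, Myo5a, of 22 glycolysis and hypoxia genes Vegfa rose and Ndrg1 fell, and of 16 circadian genes Clock rose and Per1 fell. Of 22 immediate early genes Socs3 rose, from 9.31 ± 2.82 to 46.7 ± 9.38 FPKM. Of 21 glucocorticoid-induced genes 3 fell, including Sult1a1 (85.6 ± 29.3 to 22.0 ± 6.75 FPKM), with a median of -0.36 (adjusted p = 0.00629, and adjusted p = 0.636 with an estimated correlation), and -0.07 without saline_fixed replicate 5. Of 40 ribosomal genes 3 fell, with a median of -0.50 (adjusted p = 2.1e-06, and adjusted p = 0.651 with an estimated correlation), and -0.08 with the naive libraries as the control. Among markers of other cells, S100a8 and Camp, both neutrophil granule genes, fell from 8018 ± 5106 to 1336 ± 1767 FPKM and from 1222 ± 800 to 291 ± 339 FPKM, the 2 of 13 neutrophil genes called. The neutrophil list had a median of -1.81 (adjusted p = 6.4e-05, and adjusted p = 0.636 with an estimated correlation), and -0.09 with the naive libraries as the control. Morphine_fixed replicate 4 had a list mean of 8.98, above 3 of the 4 saline libraries. The B cell list had a median of -0.85, the border macrophage list -0.39 and the monocyte list -0.28, with adjusted p of 0.0387, 0.0285 and 0.00629, and adjusted p = 0.636, 0.636 and 0.651 with an estimated correlation. The B cell shift rests on saline_fixed replicates 5 and 6, with list means of 2.21 and 2.34, while replicates 3 and 4 had 1.15 and 0.88 and the morphine libraries 0.93 to 1.09. The monocyte median was -0.06 without morphine_fixed replicate 3. The endothelial list had -0.65 (adjusted p = 0.0739). The astrocyte, oligodendrocyte and neuron lists had medians of 0.67, 0.32 and 0.43, with no call.

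Escalating-regimen morphine was compared with escalating-regimen saline in 3 libraries each. The 4 called genes were all higher in morphine (limma). None was called with all 30 libraries in the fit or with no filter on low values, and fewer were called with all 9 controls as 1 group. Lars2 rose from 31.4 ± 4.63 to 543 ± 388 FPKM (SD), a log2 difference of 3.84 ± 0.50 (SE; adjusted p = 0.0139). Hspa1a rose from 0.407 ± 0.704 to 6.48 ± 0.536 FPKM (2.52 ± 0.39, adjusted p = 0.0468), and Basp1, a membrane protein gene of growth cones, rose from 12.5 ± 0.866 to 69.0 ± 31.1 FPKM (2.29 ± 0.30, adjusted p = 0.0139). Gm10052 averaged 12.3 ± 2.78 FPKM and was listed at 0 in the 3 saline libraries. Each of the 4 was higher in 3 of 3 morphine libraries than in every saline library. In the naive libraries, Lars2 at 2163 and 3202 FPKM and Hspa1a at 10.05 and 18.11 FPKM lay above the escalating-morphine means. The homeostatic list had 18 of 25 positive members and a median of 0.55, with Jun at 45.3 ± 12.2 against 15.9 ± 2.22 FPKM and Rhob at 133 ± 26.4 against 61.8 ± 19.2 FPKM. Jun and Rhob are also on the list of immediate early genes. P2ry12 differed by -0.03 ± 0.25, Cx3cr1 by 0.09 ± 0.24 and Tmem119 by 0.50 ± 0.25, and none of them passed. The homeostatic list had an adjusted p of 0.0373, and adjusted p = 0.825 with an estimated correlation, and 10 genes were higher and 1 lower when adjusted over the list alone. The neutrophil and monocyte lists had medians of -1.04 and -0.95, each with an adjusted p of 0.00587, and adjusted p = 0.825 with an estimated correlation. Both rest largely on saline_escalating replicate 9, without which they were -0.18 and -0.14, and with the naive libraries as the control they were 0.25 and 0.30. The cell cycle list had a median of -0.08 (adjusted p = 0.0712), and Mki67 differed by 0.01 ± 0.82. At an unadjusted p under 0.05 there were 2254 genes. Without morphine_escalating replicate 1 no gene was called, without saline_escalating replicate 8 there were 465, without saline_escalating replicate 9 there were 2, and without morphine_escalating replicate 3 there was 1.

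The test of the difference between the regimens called 1 gene, Clk2, whose morphine difference was lower on the escalating regimen (adjusted p = 0.0439, limma). No size is given, since Clk2 was listed at 0 in every fixed-saline library. Lrrc25 (2.71 ± 0.49), Sun2 (2.35 ± 0.52) and Rhob (1.73 ± 0.36) had the opposite sign and did not pass, with adjusted p of 0.173, 0.221 and 0.221. At an unadjusted p under 0.05 there were 1377 genes. The count moved to 439 without morphine_escalating replicate 1, to 6 without saline_fixed replicate 4 and to 4 without saline_escalating replicate 8. It was 0 without any single fixed-morphine library, and without saline_fixed replicate 3, saline_fixed replicate 5, saline_escalating replicate 7, saline_escalating replicate 9 or morphine_escalating replicate 3.

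Averaged over both regimens (7 libraries against 7), 1965 genes rose and 514 fell under morphine, together 2479 (limma). C4b rose by 3.36 ± 0.56, Gna12, a G protein subunit gene, by 2.94 ± 0.37, Hspa1b by 2.66 ± 0.31, Tgfb1 by 2.62 ± 0.35, Hspa1a by 2.41 ± 0.26 and Vav2 by 1.94 ± 0.26. Cenpb, Enc1, Spns2 and Tesk1 rose by 1.93 to 2.52. Clec4d changed by -3.00 ± 0.53, S100a4 by -2.69 ± 0.40, H2-Eb1 by -1.58 ± 0.24, S100a10 by -1.58 ± 0.28 and Il6 by -1.41 ± 0.26. Immp1l, H3f3a, Med21, Lsm8 and 1600010M07Rik changed by -1.36 to -1.27. The groups did not overlap for 165 of the 2479 called genes and for 1.42% of all genes, where chance gives 0.0583%. The rule for named genes asks for no overlap, so all 7 morphine libraries lay on the same side of all 7 saline libraries for each of these 20 genes by selection. With the naive libraries as the control 12 of the 20 had the opposite sign: Gna12, Hspa1b, Tgfb1, Hspa1a, Cenpb, Enc1, Spns2, Tesk1, Clec4d, S100a4, H2-Eb1 and Lsm8. The homeostatic list had 6 genes higher, among them Tgfbr1 (1.12 ± 0.34) and Jun (1.09 ± 0.23), and 2 lower (median 0.12, adjusted p = 0.982). The neutrophil list had 3 genes lower and a median of -1.44 (adjusted p = 5.5e-05, and adjusted p = 0.629 with an estimated correlation), and 0.13 with the naive libraries as the control. For morphine against saline over both regimens, 1 gene was called with the naive libraries as the control (565 at an unadjusted p under 0.05), and 0 with all 9 controls as 1 group. Without morphine_escalating replicate 1 the count was 1281, and without morphine_fixed replicate 2 it was 1583.

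Whether injury and morphine acted alike was asked by testing the difference between the injury response at 7 dpi and the morphine response. The injury response was taken against the mean of the naive, fixed-saline and escalating-saline groups. The saline groups thus enter both responses and largely cancel in the difference. No gene passed (limma, 0 calls, 182 genes at an unadjusted p under 0.05), which does not show that the responses were alike. The heat shock genes Hspa1a and Hspa1b had the lowest p, with injury minus morphine at -2.18 ± 0.54 and -1.98 ± 0.59 (adjusted p = 0.927). Jun differed by -1.22 ± 0.39 and the platelet factor gene Pf4 by 1.51 ± 0.52. Across 11759 genes, injury at 7 dpi against naive and morphine against saline, which share no libraries, gave r = -0.159 and rho = -0.158. Without SNT_7dpi replicate 1 the r was 0.350, without SNT_7dpi replicate 2 it was -0.417, and without naive replicate 1 or 2 it was -0.275 and -0.022. These values of the agreement of injury and morphine changes rest on few libraries. Without SNT_7dpi replicate 2 the test of the difference called 418 genes.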

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

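The rules that flagged single libraries and differences between groups were set beforehand. Of the tests below, those of the untreated comparison, of scaling, of other cells, of single libraries and of the neutrophil list were chosen after the result was seen. The tests of transcript length and of other splits of the samples were written before their results, but the length test was first scored on all calls after the correction and then on the calls left, and the reading of a real count of 0 as undecided was added after.

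Of 33 measures tested for a library far from the rest of its group, 6 stood apart. Chance gives about 1 in 20 for normally distributed values of a single population. FPKM values need not be normal and the controls are of different kinds, so that rate need not hold here. Within the 9 controls, Apoe was 3932 FPKM in saline_escalating replicate 9, where the next value was 1457. Il1b was 89.9 FPKM in the same library, where the next value was 18.7. Mki67 was 8.24 FPKM in naive replicate 2, where the next value was 2.01. Within fixed morphine, Il1b was 9.17 FPKM in replicate 4, where the next value was 2.38, and Cst3 was 18570 FPKM in replicate 1, where the next value was 12710. Oprm1 was 1.24 FPKM in saline_fixed replicate 4 and was listed at 0 in the other 3 libraries of that group. The rule flags any group with a single value above 0, whatever the size of that value.

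Among the differences between groups, Clk2 differed between the morphine regimens by -3.19 log2 units, a fitted value that rests on zeros in all 4 fixed-saline libraries. For the difference between regimens, 16 of 100 splits of the libraries called as many genes as the real 1, and the highest of the others called 140, so chance is not excluded and the libraries hold a structure of their own. Xcl1 differed among the SNT days with an adjusted p of 0.0459.

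The genes called under fixed morphine are the pattern most open to a reading other than morphine. Of the 35 splits of the 8 libraries only the real one called 2119 genes, a share of 0.0286, and the highest of the others called 1. With 35 splits no lower share is possible, so chance is made less likely but not excluded. The lowest count over 3 scalings was 1812, which argues against scaling as the source of the number of calls. The balance of higher and lower calls was not scored and moved with the scaling. Transcript length tracked the difference (rho 0.44 across genes), and GC content hardly did (rho -0.0783). With length and GC content regressed out, 954 of the 2043 calls among the 11318 genes with a length were left (46.7%, under the share of 0.5 set beforehand), and the excess of higher genes was gone (1545 higher and 498 lower before, 651 and 662 after, new calls included). The 1089 lost calls all kept their side, with a median size of 0.99 log2 units before and 0.54 after (quartiles 0.38 and 0.71) and a median SE of 0.28 and 0.23, so they ended because the differences shrank. The 954 that were left had medians of 1.42 and 1.20. A trend with length or GC content therefore fits as a part of the differences. The correction left a median of 53.1% of the size of the lost calls and 83.1% of that of the others. Lost and left calls were divided by the test after the correction, which itself picks lost calls that shrank more. The length used was that of the longest transcript, so the correction can be incomplete and cannot decide whether length is the whole. In naive minus escalating saline, which holds no morphine library and no fixed-saline library, 95.9% of the called genes lay on the same side (69.2% of genes not called did), with medians of 0.83 for the 1595 higher genes and -0.80 for the 524 lower ones against 1.16 and -1.05 under morphine. This fits a difference of the saline libraries from the naive and fixed-morphine ones, in treatment or in library preparation or depth. It does not set saline apart from all the rest. On the first principal component saline libraries had 1.80 to 43.2, naive -14.4 and -32.6 and fixed morphine -63.2 to -34.2. Morphine_escalating replicates 2 and 3 had 13.98 and 20.88, while replicate 1 had -50.35. SNT at 1, 2 and 4 dpi had 7.86 to 89.4, on the saline side. A morphine effect of its own stays open because no batch is labelled.

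The higher cell cycle list under fixed morphine was weighed next. The largest median among lists of other cells was 0.67, for astrocytes, against 1.67, which argues against cells of another type that these lists cover; cycling cells of a type without a list stay open. Leaving out single libraries gave medians of 1.18 (without morphine_fixed replicate 3) to 2.24 (without replicate 1), so no single library carries it. Replicates 1 and 4 nevertheless had list means of 1.78 and 2.88, within the fixed-saline range of 1.61 to 2.90, and replicates 2 and 3 had 5.12 and 5.26, so an effect of morphine and a few libraries with many cycling cells cannot be told apart with 4 libraries. CCI_2dpi replicate 2 and CCI_7dpi replicate 1 also had high means, 4.67 and 5.05.

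The lower neutrophil list after injury at 7 dpi had a median of -0.87. Without saline_escalating replicate 9, which had 30884 FPKM of S100a8, it was -0.66, so that library alone is not the cause. Against the naive libraries it was 0.28 and against the saline libraries -1.26, which fits neutrophil transcripts being high in most saline libraries and not low after injury. Saline_fixed replicate 4 and saline_escalating replicate 7 had list means of 7.355 and 7.252, near the naive 7.134 and 7.16. The other saline libraries had 8.022 to 9.586. CD11b selection would retain neutrophils. Whether saline injection or the preparation of those libraries raised them was not tested.

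Other splits of the samples were counted for the remaining comparisons of at least 3 libraries per group. For escalating morphine the 10 splits are too few for a share under 0.05; the real count was 4 and the highest of the others was 1, with 1 split, the real one, reaching 4. For morphine over both regimens 1 of 100 splits, the real one, reached 2479, a share of 0.01. The highest of the others called 2143, so chance is made less likely but not excluded. The splits were drawn within each regimen, so a split could keep the real grouping of the fixed regimen. Which split called 2143 was not recorded, so that count cannot tell treatment from a structure of the libraries. For injury at 7 dpi against controls and for injury against morphine the real count was 0, which all 100 splits reach by construction, so these splits decide nothing about chance. The highest counts of other splits were 59 and 1315.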

How the results depend on the processing

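The naive libraries as the control for morphine, the removal of length and GC content, and leaving out 3 libraries with few genes were chosen after seeing the data; the others were set beforehand. The cause of a change below was not tested unless it follows from fewer samples or genes. Counts of called genes are numbers past the threshold in the comparison named. Depth is unknown, and genes near the floor of the shallower libraries limit what a low value can show. With a library left out, a group of 2 holds 1 sample, which is assumed to vary like the other groups. Sign changes of values that were called under neither setting are counted as moved values. A list counts as changed in sign where its camera test changed direction, and a median can change sign without that. Over the named genes and lists 6803 values stayed on the same side, 382 lost a call, 169 gained one, 242 moved and 41 called values changed sign.

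With a pseudocount of 0.1, SNT_1dpi against controls gave 4 calls, SNT_7dpi 0, CCI_2dpi 0, the SNT days 2 and the difference of morphine regimens 2. With a pseudocount of 5, SNT_7dpi gave 45, SNI_7dpi 1, the SNT days 6 and the models at 7 dpi 11. With no filter on low values, SNT_2dpi gave 15, SNT_4dpi 11, SNT_7dpi 84, CCI_2dpi 7, CCI_7dpi 3, SNI_7dpi 12, injury at 7 dpi 3, the SNT days 49, the models 33, SNT against CCI at 2 dpi 5, escalating morphine 0 and the regimens 0. With an FPKM of at least 5, SNT_1dpi, SNT_7dpi, CCI_2dpi and the SNT days gave 0 and the control kinds 22, with fewer genes tested.

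With quantile normalization, SNT_7dpi gave 11, CCI_2dpi and the SNT days 0 and the control kinds 78, and the homeostatic list under fixed morphine had a median of 0.16. With median-ratio scaling, SNT_7dpi gave 6, CCI_2dpi and the SNT days 0 and the control kinds 21. With TPM rescaling, SNT_7dpi gave 0, fixed morphine 3349 and the regimens 2. With array weights, SNT_1dpi gave 1, SNT_7dpi 0, CCI_2dpi 262, CCI_7dpi 1068, SNI_7dpi 25, the SNT days 0, fixed morphine 4348, the regimens 683 and the control kinds 1033. With an added minimum of 1 log2 unit, fixed morphine gave 1342 and morphine over both regimens 825. With length and GC content regressed out, fixed morphine gave 1313 (651 higher and 662 lower).

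With naive controls alone, SNT_4dpi gave 1, SNT_7dpi 0 and CCI_2dpi 0. The monocyte median became -0.069 in SNT_2dpi (where the camera test changed direction), 0.054 in SNT_4dpi and 0.028 in SNI_7dpi. The neutrophil median became 0.18 in SNT_7dpi, 0.35 in SNI_7dpi and 0.28 in injury at 7 dpi. Other medians changed sign while the camera test kept its direction: monocytes in injury at 7 dpi (0.15), neutrophils in SNT_4dpi (0.031) and CCI_7dpi (0.080), ribosomal genes in CCI_2dpi (0.049) and CCI_7dpi (0.024), antigen presentation in CCI_2dpi (0.068) and CCI_7dpi (0.026), and glucocorticoid-induced genes in SNT_2dpi (-0.11). With the replicate block the first 6 medians were -0.069, 0.054, 0.028, 0.18, 0.35 and 0.28 again, since the block leaves only the naive libraries to compare with, and SNT_1dpi gave 0, SNT_4dpi 1, SNT_7dpi 0, CCI_2dpi 0 and fixed morphine 0, with few libraries sharing a number. With saline controls alone, SNT_1dpi gave 1, CCI_2dpi 202, CCI_7dpi 231, SNI_7dpi 44 and injury at 7 dpi 563. With all 30 libraries in the fit, SNT_1dpi gave 6, the SNT days 2, fixed morphine 1135, escalating morphine 0, the regimens 0 and morphine over both 1233. With all 9 controls as 1 group, escalating morphine gave 1 and morphine over both 0.

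With the naive libraries as the control, fixed morphine gave 0, escalating morphine 2 and morphine over both 1. Differences that changed sign were, for fixed morphine, Jdp2 (-0.36), Hspa1b (-0.67), Ddit3 (0.89) and Lag3 (0.24). For escalating morphine they were Lars2 (-2.52), Hspa1a (-0.96) and the monocyte list (0.30). For morphine over both they were Gna12 (-0.29), Hspa1b (-1.44), Tgfb1 (-0.35), Cenpb (-0.52), Hspa1a (-0.73), Enc1 (-0.79), Spns2 (-0.023), Tesk1 (-0.38), Clec4d (0.15), S100a4 (0.49), H2-Eb1 (0.43), Lsm8 (0.20), and the antigen presentation (0.27), ribosomal (0.20) and monocyte (0.39) lists. Medians that changed sign while the test kept its direction were, for fixed morphine, antigen presentation (0.20) and monocytes (0.087), for escalating morphine, neutrophils (0.25), and for morphine over both, neutrophils (0.13) and disease-associated genes (0.098).

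Leaving out the 3 libraries with few detected genes, SNT_2dpi gave 2, SNT_7dpi 53, CCI_2dpi 3, injury at 7 dpi 843, the SNT days 8, the models 5, SNT against CCI 1 and the control kinds 689. The neuron list in SNT_2dpi had a median of -0.22, and the agreement of injury and morphine was r = 0.350. With an estimated correlation 0 of 89 list calls were left.

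Leaving out single libraries gave 2 (for example without naive replicate 1) to 1221 (without SNT_1dpi replicate 2) calls for SNT_1dpi, 0 to 1143 for SNT_2dpi (without SNT_2dpi replicate 1), 0 to 1 for SNT_4dpi, 8 (without saline_fixed replicate 6) to 1006 (without SNT_7dpi replicate 2) for SNT_7dpi, 0 to 1 for CCI_2dpi, 0 to 100 for CCI_7dpi (without CCI_7dpi replicate 2) and 0 to 2 for SNI_7dpi. It gave 0 to 437 for injury at 7 dpi (without SNT_7dpi replicate 1), 0 to 546 for the SNT days (without SNT_2dpi replicate 1), 0 to 792 for the models and 0 to 418 for injury against morphine (both without SNT_7dpi replicate 2), 0 to 1779 for SNT against CCI (without SNT_2dpi replicate 1) and 0 to 51 for the control kinds. For morphine it gave 757 to 2163 on the fixed regimen (757 without morphine_fixed replicate 2), 0 to 465 on the escalating regimen (0 without morphine_escalating replicate 1), 0 to 439 for the regimens (439 without it) and 1281 (without it) to 2722 over both. The agreement of injury and morphine ran from -0.417 to 0.350 and that of injury models and days from -0.138 to 0.171. Lists whose camera test changed direction were the monocytes in SNT_2dpi (-0.95 to -0.43), the neurons in SNT_2dpi (-0.22 to 0.71), the neutrophils in SNT_7dpi (-1.31 to -0.046), the cell cycle in CCI_2dpi (-0.085 to 2.54) and cholesterol synthesis in CCI_7dpi (0.053 to 1.10). Medians that changed sign while the test kept its direction included disease-associated genes under fixed morphine (0.069 without saline_fixed replicate 6), ribosomal genes under morphine over both (0.059 without morphine_escalating replicate 1), antigen presentation and glucocorticoid-induced genes in CCI_2dpi (0.026 and 0.017 without CCI_2dpi replicate 2) and glucocorticoid-induced genes in injury at 7 dpi (0.14 without SNT_7dpi replicate 2).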

Other observations

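A few single genes varied widely between libraries. Rn45s, the ribosomal RNA precursor, spanned 0 to 17746 FPKM over the libraries, with 14726 and 13976 FPKM in SNT_2dpi and 2295 and 0 FPKM in CCI_2dpi. Lars2 was 5148 FPKM in CCI_2dpi replicate 2, 3367 and 3104 FPKM in SNI_7dpi, and 20.2 and 28.0 FPKM in SNT_4dpi. Within SNT_7dpi it was 23.3 FPKM in replicate 1 and 1030 FPKM in replicate 2. Gngt2, a G protein subunit gene, was listed at 0 in all 4 fixed-morphine and all 4 CCI libraries and was 275 FPKM in SNT_2dpi replicate 2.

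The replicates of SNT_7dpi lay far apart in Cst3, C4b and Slc39a14. Replicate 1 had 66554 FPKM of Cst3 and 8466 detected genes, and replicate 2 had 16911 FPKM and 10352 genes. C4b was listed at 0 in replicate 1 and was 21.7 FPKM in replicate 2, and Slc39a14 was listed at 0 and 31.4 FPKM. Within escalating morphine, replicate 1 had 15103 FPKM of Cst3 and replicates 2 and 3 had 42604 and 40240 FPKM.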
